A study of Homo sapiens with 6 samples.

How the data were processed

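RNA-seq was analysed from 6 samples of MDA-MB-435 cells, 3 controls and 3 with knockdown of ZCCHC24, grouped by their titles. Per the labels' protocols, libraries were made from 1 ug of total RNA with a stranded mRNA kit, a type that selects poly(A) RNA, and sequenced as paired reads of 100 bases; how the knockdown was made is not given in the sources used here. The deposited table holds FPKM values, which are fragment numbers scaled by transcript length and by the mapped fragments of the library, for 57150 genes with 1 column per sample, per the file headers. TopHat 1.4.1, Cuffdiff 2.2.0 and the hg19 build are named in the submitters' processing notes, without saying which step used which. The annotation, the filters and any scaling between libraries are not given in the sources used here. FPKM divides by transcript length and by total fragments, so values of very short genes are unstable, and a large change in abundant genes shifts all others. Coordinates are hg19 loci as the table gives them; many loci span neighbouring genes, so they can be wider than the gene. The table held no fold changes or p-values of the authors and 1 blank row, which was left out.

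All FPKM columns were matched to samples by name. Genes with a mean of at least 1 FPKM over the 6 samples were kept (13343), a pseudocount of 1 was added, and log2 values were fitted with limma 3.58.1 in R 4.3.3, using its empirical Bayes moderated test with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on log2(FPKM + 1) understates the change of weakly expressed genes; folds quoted as ratios are ratios of mean FPKM. FPKM are not counts, so no count model was used. The values of weak genes fell on steps, whose most frequent ratio between libraries, among genes below 0.2 FPKM, gave the relative depth; absolute depth is unknown and no counting intervals are given.

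Before the data were examined, 19 gene lists, the test, the alternatives and the rule for named genes were fixed. The rule took ZCCHC24, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and the 3 members of each list with the largest called change; some genes that it names are not reported here. Lists were matched by symbol, tested with camera at a preset inter-gene correlation of 0.01, with p adjusted over the 19 lists, and again with an estimated correlation and with fry, whose directional test asks whether a list's genes move one way on balance. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median scaling, a replicate block, sample quality weights and leaving out each library. Gene types and lengths came from GENCODE v29 by Ensembl ID (12941 of the tested genes matched), without using its coordinates beside those of the table.

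The fit was tested on simulated data with the observed means and spread of the 13343 genes, of which 200 were changed. It recovered 98% of genes changed by 1 or 2 on the log2 scale, 70% at 0.5 and 10% at 0.25, with 8 false calls among 146. A first version of the simulation recovered 88% at a change of 1, below the 90% that had been set, because falls placed on weak genes were truncated at 0; falls were then placed only on genes able to hold them. The 1 shifted list was called and 0 of 18 unshifted lists were. The simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes would be called falsely. The recovery rates hold for 200 changed genes, far fewer than were called in the real data.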

Results

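Poly(A)-selected, strand-specific RNA-seq libraries were made from MDA-MB-435 cells, an established human cancer line, with reduced ZCCHC24 or from their controls. ZCCHC24 is a CCHC-type zinc finger protein, and the series title places it in the study of the splicing machinery. The labels give breast as the tissue of the line; as background, genotyping has since assigned MDA-MB-435 to a melanoma origin. There were 3 control and 3 knockdown libraries, and nothing in the labels says whether they came from separate cultures, so p-values measure the spread between these libraries only. The deposited table gave one FPKM value per gene and library for 57150 genes, of which 13343 had a mean of at least 1 FPKM over the 6 libraries and were tested. Read totals were not part of the table. The steps between the lowest values showed that 1 fragment was worth at most 1.27 times as much in the shallowest library, control 2, as in the deepest, knockdown 3, so the relative depths were close while the absolute depth is unknown. Across the tested genes, libraries of one group correlated with r of 0.986 to 0.988 and libraries of different groups with r of 0.927 to 0.932 on log2(FPKM + 1). In what follows, levels are mean FPKM ± SD over n = 3 libraries, fold changes are knockdown minus control on log2(FPKM + 1) with the standard error of the fit, and adjusted p-values come from limma with Benjamini-Hochberg correction over the tested genes unless stated otherwise.

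ZCCHC24 (ENSG00000165424; hg19 chromosome 10, 81142080 to 81205383) fell from 12.7 ± 0.468 FPKM in the controls to 1.68 ± 0.132 FPKM after knockdown, which left 13.2% of the control level. The log2 fold change was -2.36 ± 0.08 with a limma adjusted p of 1.5e-07. Every knockdown library lay below every control library, with values of 1.54, 1.69 and 1.81 FPKM against 12.7, 12.3 and 13.2 FPKM. An exact two-sided permutation test of these values gave p = 0.1, the smallest that 3 against 3 libraries allow.

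Knockdown was accompanied by lower levels of the cell division genes and by changes in both directions across most of the expressed genome. At a limma adjusted p below 0.05, 4937 genes were higher and 4730 were lower, together 72.5% of those tested, and 3676 did not pass. Among these, 662 genes rose and 953 fell by at least 1 on the log2 scale (1012 and 1263 with a pseudocount of 0.1), and the median absolute change of the called genes was 0.55. In 75.9% of tested genes the groups did not overlap, against 10% expected by chance for 3 against 3 libraries. The median change of all tested genes was 0.01.

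**Figure D1:**
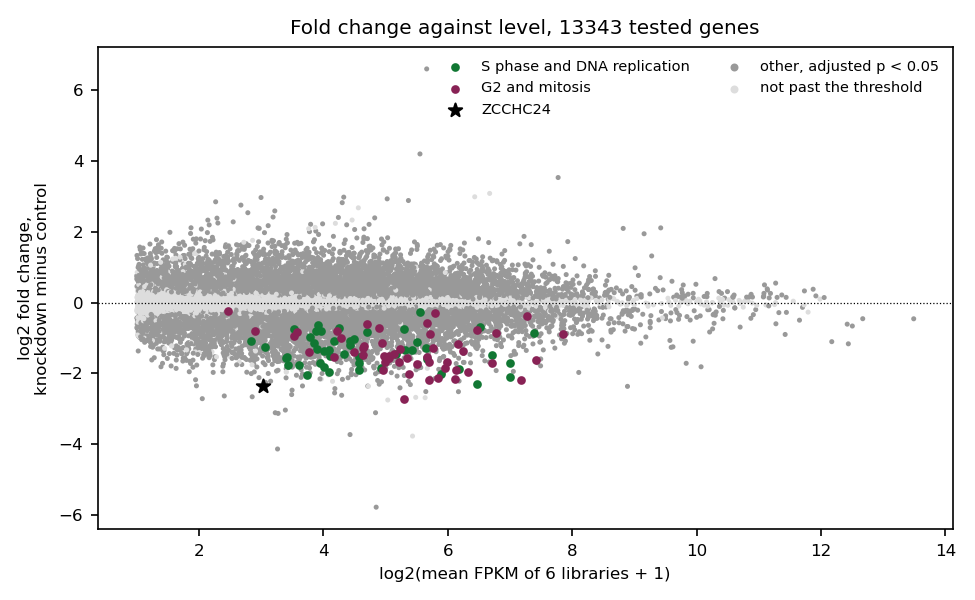
Log2 fold change (knockdown minus control, on log2(FPKM + 1)) against log2(mean FPKM of the 6 libraries + 1) for the 13343 tested genes, each point 1 gene, dark grey where the limma adjusted p was below 0.05. The 47 S phase genes (green) and 50 G2 and mitosis genes (purple) all lie below 0, and ZCCHC24 (star) is at -2.36.

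Genes of DNA replication and mitosis fell without exception among those tested. All 47 members of the S phase and DNA replication list fell, with a median log2 fold change of -1.32, and all 50 members of the G2 and mitosis list fell, with a median of -1.46. RRM2, a subunit of ribonucleotide reductase, went from 146 ± 11.5 to 28.6 ± 1.70 FPKM. TYMS, the thymidylate synthase, went from 207 ± 4.92 to 47.9 ± 4.97 FPKM. Among mitotic genes, HMMR, a spindle-associated protein, fell 7.14-fold from 67.4 ± 2.07 to 9.44 ± 1.13 FPKM. BIRC5 (survivin) fell 4.72-fold to 17.8 ± 0.918 FPKM, and UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell 4.57-fold to 51.8 ± 3.26 FPKM. The counts were the same when adjusted over the list alone, 47 and 50. As sets relative to other genes, both lists were lower by camera with a preset inter-gene correlation of 0.01, with p adjusted over the 19 lists of 2.7e-17 for S phase and 8.4e-18 for G2 and mitosis. These set calls did not hold with an estimated correlation, where the adjusted p = 0.15 for S phase and adjusted p = 0.16 for G2 and mitosis.

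Genes of the splicing machinery changed in both directions, and camera called neither of their lists. Of 77 core spliceosome genes, 32 rose, 32 fell and 13 did not pass, with a median log2 fold change of 0.05. The members with the largest changes fell. TXNL4A, a protein of the U5 snRNP, went from 111 ± 12 to 29.9 ± 0.245 FPKM, PPIH, a cyclophilin of the tri-snRNP, from 57.7 ± 1.66 to 19 ± 1.57 FPKM, and LSM4, of the LSM ring that binds U6, from 92.4 ± 6.68 to 36.3 ± 1.38 FPKM. The list's median and test were positive while its mean was -0.04, and camera gave an adjusted p of 0.96. Of 82 splicing regulators, 25 rose, 37 fell and 20 did not pass, with a median of -0.08 and a camera adjusted p of 0.44; fry, which does not compare with other genes, called this list lower (adjusted p 0.018). The kinases SRPK2 and CLK1, which phosphorylate SR proteins, rose 2.85-fold to 76.5 ± 3.01 FPKM and 2.73-fold to 51.0 ± 0.743 FPKM. TAF15, an RNA-binding protein of the FET family, fell 2.61-fold to 21.5 ± 1.03 FPKM. The values are sums per gene, so the isoforms made from each gene were not analysed here.

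Transcripts known as targets of nonsense-mediated decay were mostly higher. Of 32 such transcripts, 22 rose, 5 fell and 5 did not pass, with a median log2 fold change of 0.39. The members named by the largest change are also genes of stress responses. SESN2, which is induced by stress and restrains mTORC1, rose 7.63-fold from 1.88 ± 0.0624 to 14.4 ± 0.374 FPKM, GADD45B, a stress-induced growth arrest gene, rose 3.40-fold to 10.1 ± 0.804 FPKM, and ATF5, a stress-responsive transcription factor, rose 2.90-fold to 36.8 ± 1.34 FPKM. The list shares 8 members with the stress response list described further on. Camera gave an adjusted p of 0.0013 for the 32 transcripts, and the call did not hold with an estimated correlation (adjusted p = 0.22). Of 21 factors of nonsense-mediated decay and the exon junction complex, 10 rose, 5 fell and 6 did not pass, with a camera adjusted p of 0.39. UPF2, a core factor, rose to 16.7 ± 0.614 from 8.40 ± 0.975 FPKM and SMG8 rose to 17.2 ± 0.169 from 10.5 ± 0.432 FPKM, whereas MAGOHB fell to 18.7 ± 1.82 from 29.3 ± 2.23 FPKM.

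Most tested genes of the melanocyte lineage list and of the sterol synthesis list fell after knockdown. In the melanocyte lineage list, 15 of 24 genes fell, 5 rose and 4 did not pass, with a median log2 fold change of -0.33. PMEL, the structural protein of melanosomes, fell from 89.5 ± 6.33 to 19.5 ± 0.145 FPKM and TYRP1, an enzyme of melanin synthesis, from 196 ± 1.37 to 58.6 ± 1.23 FPKM. CAPN3, a calpain, fell from 278 ± 13.5 to 80.0 ± 1.68 FPKM. The list also holds the cell cycle kinase CDK2, which is among its falls. Camera gave an adjusted p of 0.011, which was lost with an estimated correlation (adjusted p = 0.45). In the breast epithelial list only 15 genes were expressed highly enough to be tested; 4 rose, 3 fell and 8 did not pass, and camera gave an adjusted p of 0.96. ERBB3, a receptor of the EGFR family, fell to 21.7 ± 0.921 FPKM and ITGA6, an integrin, to 31.7 ± 1.10 FPKM, while ALDH1A1, an aldehyde dehydrogenase, rose to 53.6 ± 0.600 FPKM. Of 24 genes of cholesterol and sterol synthesis, 17 fell, 1 rose and 6 did not pass, with a median of -0.55. SREBF2, the transcription factor of the pathway, fell 2.43-fold to 50.4 ± 0.326 FPKM and LSS, lanosterol synthase, fell 2.10-fold to 18.1 ± 1.35 FPKM. The camera adjusted p was 0.00027, and the call did not hold with an estimated correlation (adjusted p = 0.15).

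**Figure D2:**
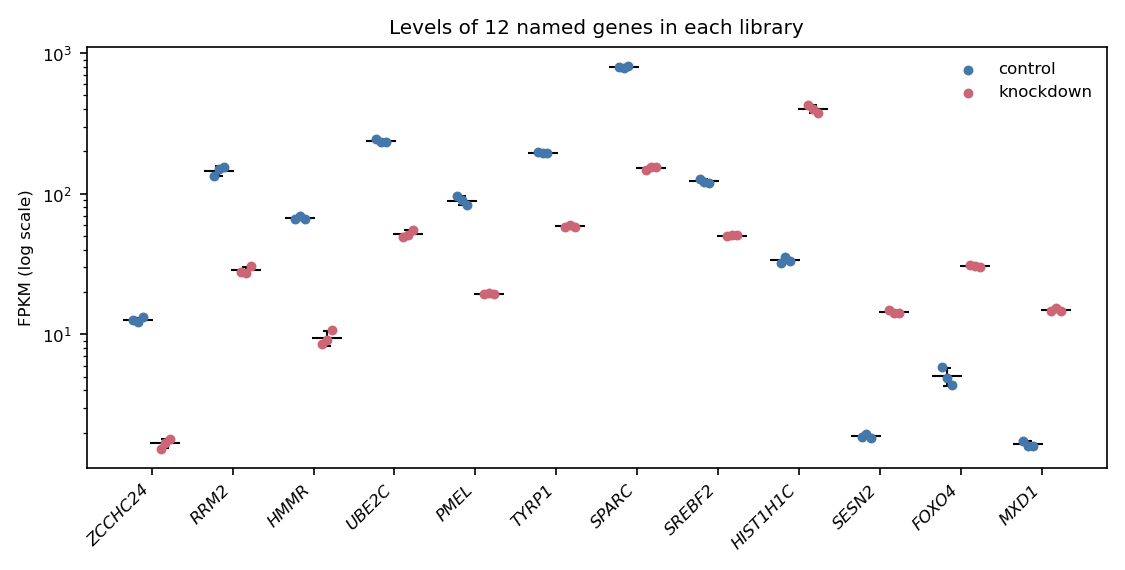
FPKM of 12 named genes (log axis) in each of the 3 control (blue) and 3 knockdown (red) libraries, with the mean and SD as a black dash and bar. ZCCHC24, RRM2, HMMR, UBE2C, PMEL, TYRP1, SPARC and SREBF2 lie lower and HIST1H1C, SESN2, FOXO4 and MXD1 higher in all 3 knockdown libraries.

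The matrix, hypoxia, stress response, p53, immediate early, interferon and NF-kB lists held genes changed in both directions and were not called by camera. Fry called each of these 7. It does not compare with other genes, and 72.5% of all tested genes were called, so its calls do not set these lists apart. Among 38 tested genes of the extracellular matrix and mesenchymal list, 19 fell, 12 rose and 7 did not pass (camera adjusted p 0.12). SPARC, a matricellular protein, fell 5.17-fold from 793 ± 15.1 to 153 ± 4.72 FPKM, THBS1 (thrombospondin) fell 5.94-fold to 20.5 ± 0.700 FPKM and LOXL2, a lysyl oxidase, fell 4.29-fold to 2.41 ± 0.305 FPKM. Of 33 hypoxia and glycolysis genes, 18 fell and 8 rose (camera adjusted p 0.074); LDHA, lactate dehydrogenase, fell 3.28-fold from 1396 ± 64.1 to 425 ± 13.4 FPKM and PFKP, a phosphofructokinase, to 43.3 ± 0.967 FPKM, while the histone demethylase KDM3A rose to 45 ± 1.99 FPKM. The unfolded protein and integrated stress response list was divided, with 16 genes higher and 16 lower of 35 (camera adjusted p 0.96) and a negative median beside a positive mean and test. Its largest changes were rises, of SESN2, of CHAC1, which degrades glutathione, 7.62-fold to 6.0 ± 0.158 FPKM, and of HERPUD1, a factor of ER-associated degradation, 3.22-fold to 67.9 ± 1.53 FPKM. Of 26 p53 targets, 12 rose and 7 fell (camera adjusted p 0.59); BBC3 (PUMA) rose to 11.8 ± 0.585 FPKM and TP53I3 fell to 4.72 ± 1.06 FPKM. Of 29 immediate early and heat shock genes, 15 rose and 11 fell (camera adjusted p 0.44), with rises of DUSP5 to 17.3 ± 1.15, IER2 to 66.0 ± 2.05 and FOSB to 4.66 ± 0.450 FPKM. Of 48 interferon-stimulated genes, 16 rose and 17 fell (camera adjusted p 0.84): ISG15 rose to 168 ± 3.72 FPKM, whereas OAS3 fell to 3.62 ± 0.261 and UBE2L6 to 20.6 ± 0.406 FPKM. Of 16 NF-kB and inflammatory genes, 8 rose and 6 fell (camera adjusted p 0.84); IL8 fell to 3.28 ± 0.475 and TNFAIP3 to 11.8 ± 0.971 FPKM, and MMP1 rose to 11.0 ± 0.562 FPKM.

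Of 78 cytosolic ribosomal protein genes, 34 rose, 12 fell and 32 did not pass, with a median of 0.09 (camera adjusted p 0.089); the named rises were RPS13 to 1545 ± 35.5, RPL11 to 2934 ± 57.7 and RPS28 to 20.4 ± 2.0 FPKM. Ribosomal protein genes have many near-identical pseudogenes, so their values depend on how shared reads were assigned. Of 76 nuclear genes of the respiratory chain, 23 rose, 25 fell and 28 did not pass (camera adjusted p 0.96). COX7C, a subunit of cytochrome c oxidase, stood apart at 1113 ± 56.6 against 257 ± 6.24 FPKM, a 4.33-fold rise, while NDUFA12 and NDUFS8 of complex I fell to 49.4 ± 1.34 and 57.7 ± 4.76 FPKM. Histone genes of the replication-dependent clusters were divided: 25 of 51 fell, 14 rose and 12 did not pass (camera adjusted p 0.44, direction lower; fry adjusted p 0.044, direction higher). The linker histone gene HIST1H1C (hg19 chromosome 6, 26055967 to 26056699) rose 11.9-fold from 33.8 ± 1.71 to 402 ± 25 FPKM and HIST1H2AC rose 8.02-fold to 71.6 ± 3.61 FPKM, whereas HIST1H4A fell 7.01-fold to 2.57 ± 1.36 FPKM. Most mRNAs of this class lack a poly(A) tail, and the libraries were poly(A)-selected, so their levels reflect only the part that was captured. Adjusted over the list alone, the counts differed from those over all genes for 3 lists. They became 12 rises and 8 falls for the p53 targets, 13 and 19 for the matrix list, and 6 and 16 for the melanocyte list.

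**Figure D3:**
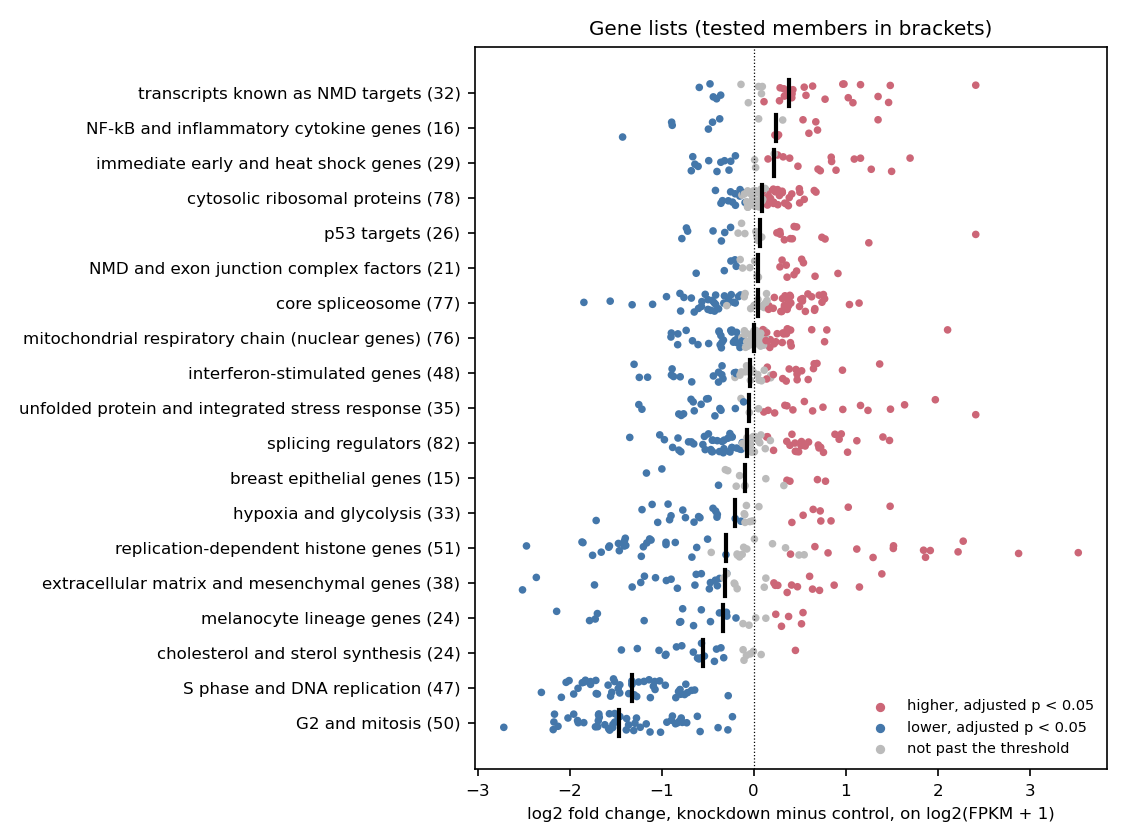
Log2 fold change (knockdown minus control, on log2(FPKM + 1)) of each tested member of the 19 gene lists, 1 point per gene, red where higher and blue where lower at a limma adjusted p below 0.05, grey otherwise; black bars are list medians and the number of tested members is in brackets. The medians of the S phase and G2 lists lie at -1.32 and -1.46, and those of the other lists between -0.55 and 0.39.

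Beyond these lists, the largest rises among genes with separate groups included MXD1, an antagonist of MYC at shared binding sites, which rose 9.04-fold to 15.0 ± 0.461 FPKM, and FOXO4, a forkhead transcription factor, which rose 6.11-fold to 30.8 ± 0.492 FPKM. MAP3K7CL rose 15.4-fold from 0.659 ± 0.227 to 10.1 ± 0.481 FPKM. The noncoding gene AC058791.1 rose 8.62-fold to 56.6 ± 4.01 FPKM, and the pseudogenes AP000580.1 and COX7CP1 rose to 34.6 ± 4.96 and 10.6 ± 2.59 FPKM; COX7CP1 can share reads with its parent COX7C. AP001421.1 rose to 7.45 ± 1.69 FPKM and was listed at 0, 0 and 0.564 FPKM in the controls. RP11-820L6.1 rose to 31.0 ± 3.27 FPKM, with controls at 0.272, 3.28 and 15.9 FPKM. The small RNA gene RNY1 was listed at 0 in the 3 controls and at 138, 77.5 and 81.6 FPKM in the knockdown libraries.

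The largest falls included TTLL12, a tubulin tyrosine ligase-like protein, 10.2-fold to 4.95 ± 0.219 FPKM, VCAN (versican, a matrix proteoglycan), 13.5-fold to 1.31 ± 0.475 FPKM, and the matrix protease ADAMTS14, 11.7-fold to 0.986 ± 0.229 FPKM. HMMR, CDCA7L and OIP5 were also among them; CDCA7L fell 7.18-fold to 4.55 ± 0.950 FPKM and OIP5, a centromere protein, fell 8.35-fold to 2.19 ± 0.123 FPKM. UBAP1L fell 6.98-fold to 4.29 ± 0.266 FPKM. IFI30, a lysosomal thiol reductase, fell from 38.7 ± 3.89 FPKM to 1.31, 1.06 and 4.66 FPKM in knockdown libraries 1 to 3, and its listed locus is shared with a neighbouring gene. The pseudogene AC000041.8 fell from 8.01 ± 2.64 FPKM to 1.80 FPKM in knockdown 2 and was listed at 0 in the others. The sense-intronic RP11-496N12.6 fell from 6.21 ± 1.18 FPKM to 0.217 and 0.0673 FPKM in knockdown 2 and 3 and was listed at 0 in knockdown 1. RNA5S9 and SNORA70 were listed at 0 in the 3 knockdown libraries, against 44.0, 77.8 and 45.1 FPKM and 22.6, 18.1 and 10.9 FPKM in the controls. As a class, such short RNAs lack a poly(A) tail and are poorly captured by poly(A) selection.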

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

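All alternatives in this part were planned. In the 12 refits 50% to 52.3% of calls were rises, but median scaling centres the changes, so the balance under it was largely set by the method. Of the 9667 main calls, 7896 to 9643 were called with the same sign and 0 with the opposite sign. The lowest number, at a filter of 5 FPKM, comes from fewer genes tested. Leaving out 1 library gave 4568 to 4787 higher and 4470 to 4568 lower genes. With a pseudocount of 0.1, 1012 genes rather than 662 rose and 1263 rather than 953 fell by at least 1, as a smaller pseudocount shrinks weak genes less. ZCCHC24 stayed between -2.39 and -2.32 with any library left out. The labels do not say whether the numbers pair the samples. Same-numbered libraries had deviations correlated at -0.03, -0.07 and 0.02, so no shared deviation was seen, which cannot exclude pairing. The replicate block called 4971 higher and 4773 lower genes and changed no set call. RP11-820L6.1 missed the threshold without the filter (log2 fold change 2.82, adjusted p = 0.050); no other named gene changed side or sign in the refits that tested it. At the filter of 5 FPKM, 5 named genes were not tested (AP001421.1, RP11-496N12.6, AC000041.8, CHAC1 and FOSB).

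The set tests depended on how camera was run and on the choice of test. All 5 called lists were lost with an estimated correlation (0 lists called), with adjusted p of 0.22 for decay targets, 0.15 for S phase, 0.16 for G2 and mitosis, 0.15 for sterol synthesis and 0.45 for the melanocyte list. Over the other 13 alternatives these 5 lists stayed called, with highest adjusted p of 0.0022, 7.9e-06, 7.9e-06, 0.00054 and 0.018 in that order. Fry, which does not compare with other genes, called 15 lists, adding splicing regulators (adjusted p 0.018), decay factors (0.00029), p53 targets (0.00032), interferon-stimulated genes (0.014), NF-kB genes (0.0074), the unfolded protein list (0.00017), hypoxia (4.0e-05), matrix (3.8e-05) and immediate early genes (0.00011). It reversed the histone list (0.044, higher), the core spliceosome (0.31, lower) and the respiratory chain (0.62, higher). Hypoxia genes were also called without the filter (0.0054). Under other settings of camera, directions turned without the filter for the core spliceosome and the unfolded protein list (both 0.93), at 5 FPKM for the histone, unfolded protein and breast epithelial lists (all 0.99), under the block for the unfolded protein list (0.98), and with quality weights for the breast epithelial and respiratory chain lists (both 0.99). With 1 library left out, adjusted p ran from 0.88 to 0.997 for breast epithelial genes, 0.74 to 0.997 for the respiratory chain, 0.95 to 0.997 for the core spliceosome and 0.025 to 0.32 for ribosomal proteins, which were called only without control replicate 1 (0.025). The causes of these changes were not tested. DESeq2 and a comparison with calls of the authors were not run, since the table holds neither counts nor calls. Absolute depth is unknown, so no limit of detection can be given for genes listed at 0.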

Other observations

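Tests on the gene length trend, the genes outside the division lists, the comparison with other noncoding genes, the share of histone genes that rose and the splits of the samples were chosen after their results were in part seen, as were the genes named in this part. CDKN1B (p27), an inhibitor of cyclin-dependent kinases, rose from 9.56 to 26.9 FPKM (log2 fold change 1.41, limma adjusted p 3.6e-07). E2F1, an activator of S phase genes and itself a member of the S phase list, fell from 24.6 to 7.99 FPKM (-1.51, limma adjusted p 2.1e-07). CDK2, a member of the melanocyte lineage list, fell from 125 to 37.9 FPKM (limma adjusted p 1.7e-07). MKI67, of the G2 and mitosis list, fell from 75.9 to 30.8 FPKM (limma adjusted p 1.1e-06). MYC, of the immediate early list, fell from 57.8 to 36.7 FPKM (limma adjusted p 4.7e-06). FOXO3 and FOXO1, relatives of FOXO4, rose to 12.7 and 8.61 FPKM (adjusted p 2.0e-05 and 0.00025). The lineage factor MITF fell from 183 to 116 FPKM and MLANA from 172 to 98.1 FPKM, whereas TYR, tyrosinase, measured 204 and 207 FPKM (adjusted p 0.64).

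Among gene types, the nuclear noncoding RNAs MALAT1 and NEAT1 rose from 171 to 730 FPKM and from 106 to 289 FPKM. The 7 pseudogenes of mitochondrial origin that share a locus on chromosome 1 (hg19, 536815 to 755214) all fell, from MTND2P28 at -0.13 to hsa-mir-6723 at -1.16, and their share of all FPKM was 6.46% to 6.96% in the controls and 4.41% to 4.53% in the knockdown libraries. The table holds 0 genes with an MT- symbol, and whether these values come from mitochondrial transcripts was not tested.

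The first pattern weighed is the number of changed genes and the fall of division genes. Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 split) called as many genes. It called 9667, against 1 in the highest of the others. The other splits mix controls and knockdowns, so the real difference adds to their spread and leaves few calls. They give no estimate of calls made by chance, and 10 splits are too few for a share under 0.05. The median log2 fold change of the 97 division genes was -1.39, with an SE of 0.07 from a bootstrap over genes, which treats them as independent. After the trend on exonic length was removed, the median was -1.39 in the 96 genes with a length, which argues against that trend as its cause. Median scaling gave -1.40 but moved the median of all tested genes by only -0.01, so it tests nothing; the 13246 genes outside these lists had a median of 0.016 (SD 0.67), which argues against a single factor per library as the whole cause, since it would move them alike. The labels give no batch or culture date.

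The second is the rise of sense-intronic transcripts, which lie inside introns of other genes: 37 of 62 rose and 3 fell, with a median log2 fold change of 0.54. This lay 0.49 above the median of 0.05 of 700 lincRNA and antisense genes of the same FPKM range, which changed in both directions (SD 0.71). A permutation test of the difference gave p = 1e-05, the smallest that the permutations can give. That met the rule written for it, a difference above 0.2 with p below 0.05. However, the class was picked for its median and the rule was written afterwards. In the 700 lincRNA and antisense genes, the median of 0.05 still argues against an equal rise of all weak noncoding genes. Sense-overlapping genes (15 of 24 rose, summed control FPKM 58.3) had a higher median of 0.60, so a rise shared with that class stays open. The type misc_RNA (7 of 17 rose) also had a higher median, 0.74. Its summed FPKM was 1185 in the controls and 970 after knockdown, so it is not counted here as a weak class. The 56 sense-intronic genes with a tested host had a host median of 0.37. The transcripts exceeded their hosts by a median of 0.19 (38 of 56 higher), short of the 0.2 set in advance, so host levels stay open as part of the cause. A sign-flip permutation of the mean difference, 0.23, gave p = 0.0024, treating the genes as independent. The nuclear RNAs FTX, TUG1 and CDKN2B-AS1, not looked at before, had a median of 0.49, which is the value of CDKN2B-AS1. KCNQ1OT1 and MEG3, chosen with them, were not among the tested genes. The median lay above the 0.2 set in advance for more nuclear RNA in the knockdown libraries as a candidate explanation. A further requirement, that the median gene pass the limma test, was added after the values were seen; only FTX (1.68) passed, with adjusted p of 0.092 for TUG1 and 0.13 for CDKN2B-AS1, so it is left open.

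The third is the division among histone genes. The 14 risen genes, 27.5% of those tested, compare with 37% of all tested genes, so this share does not decide whether fewer dividing cells alone account for the list; the bound of 5% set for it was too low. A candidate explanation is polyadenylated histone transcripts, which poly(A) selection retains. The 15 genes with an annotated transcript over 1000 nt had a median higher by 0.74 than the 36 others, but a permutation test gave p = 0.22, so it stays open; 26 of the 51 were matched to the annotation by symbol, since their IDs had changed, a step added after the test on the 25 matched by ID had been seen and was void for covering too few.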
